A study of Mus musculus with 62 samples.

How the data were processed

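The series holds RNA sequencing of 62 mouse samples in 15 groups. Per the labels, 5 tissues were taken at postnatal day 21 (P21) from mice in which Nova1, a gene of a neuronal RNA-binding protein, was deleted in inhibitory neurons (labelled cKO), and from mice labelled cHet, which served as the control genotype. The tissues were hypothalamus, periaqueductal gray, caudate putamen and substantia nigra (n = 4 per genotype) and pituitary (n = 3 per genotype). Per the labels, translating ribosome affinity purification (TRAP), which pulls down tagged ribosomes of chosen cells with their mRNA, was done on whole brain at P0 (n = 6 per genotype). Primary neurons from the ventral diencephalon and mesencephalon of e13.5 embryos were infected with lentivirus on day 7 in vitro and taken for RNA on day 14, per the labels' protocols. They received GFP (labelled WT), GFP with Cre recombinase (labelled Nova1 KO) or GFP, Cre and Impact (n = 4 each). Impact is an inhibitor of the kinase GCN2, which phosphorylates eIF2 under amino acid shortage, and is described in the labels as a Nova1 target. Per the labels' protocols, RNA was extracted with Trizol and RNeasy columns and made into TruSeq libraries after polyA selection.

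Each deposited table lists 23038 genes by Entrez number and symbol with the exon length, a tag number and an RPKM value. In 6 tables, those of pituitary, the deposited tag numbers are whole and were taken as counts. In the other 56 tables, between 4.56% and 18.8% of genes have a fractional deposited tag number, so these were taken to be estimated counts and rounded to whole numbers before testing. The deposited RPKM values equal the tag number scaled by exon length and by the library's tag total (largest relative difference 1.07e-12 percent) and were used only in that check. Per the submitters' processing notes, the genome build was mm10 and edgeR was used; the aligner, the counting program and the annotation are not given in the sources used here. How the authors treated reads that match several places is not given either, so genes with near-identical copies, such as Hbb-b1, H2-D1 and ribosomal protein genes, and overlapping genes on opposite strands are uncertain. Counts are per whole gene, so Nova1 tags can come from exons outside the deleted part. Of the Entrez numbers, 22959 were found in a RefSeq table of GRCm38, and gene positions were taken from GENCODE M21 on GRCm38.

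Total tags per library ran from 2.24 to 29.5 M (megatags; median 19.2 M), with the lowest totals in pituitary. The precision of the tests was measured on simulated counts with the real means and library sizes, in which 200 genes were changed. For genes changed 2-fold, the share recovered was 92.5% in hypothalamus, 86.6% in periaqueductal gray, 88.1% in caudate putamen, 91.0% in substantia nigra, 46.3% in pituitary and 94.0% in TRAP. In primary neurons it was 70.1% for KO against WT, 82.1% for added Impact against KO and 89.6% for added Impact against WT. A simulated shift of 0.3 log2 units in a gene list was called with the preset correlation in all 9 comparisons, and with an estimated correlation in 8, the exception being pituitary (adjusted p = 0.231). The simulated genes were drawn independently of each other. For lists whose genes vary together, this run cannot tell how often either test would call a true shift.

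Genes were kept with filterByExpr (minimum count 10, minimum total 15), scaled by the trimmed mean of M values, and tested with edgeR 4.0.16 (quasi-likelihood F test) within R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, with 0.05 as the threshold, and "changed", "rose" and "fell" refer to it. Each tissue and the TRAP samples were fitted separately, and the 3 groups of primary neurons were fitted together. A fit over the 4 brain regions gave the average effect of genotype and its interaction with region. Levels are CPM (counts per M of scaled library size) as mean ± SD, and log2 fold changes have their standard error (SE). Overlaps were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the overlaps computed.

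The design, the tests, 34 gene lists and the rule for naming genes were chosen before the data were examined. The lists cover stress responses, peptides and hormones, classes of neurons, glial, vascular and blood cells, and metabolic, synaptic and ribosomal genes. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 3) with a preset correlation of 0.01, adjusted over the lists of a comparison, where at least 5 members were measured, which made 301 tests. Beside each call stands the adjusted p of camera with a correlation estimated from the data. In the 66 calls of the preset test, the median, the mean and the test had the same sign. With an estimated correlation, 0 of the 301 tests passed (lowest adjusted p = 0.142), and fry, which asks whether the genes of a list move in a single direction on balance without comparing them with other genes, called 11 of the 66. Of the 34 lists, 10 were called in no comparison (lowest adjusted p between 0.065 and 0.254).

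The rule for naming genes took Nova1 and Impact always. It then took up to 10 genes that rose and 10 that fell by size of log2 fold change among genes past the threshold with a mean log2 CPM of at least 1 and groups that do not overlap. Up to 4 further members per list followed by smallest adjusted p, with the hormone, transmitter and stress genes that are the subject of each tissue. From these, genes whose call held when any single library was left out were preferred. Cirbp, Hsph1, the Slc7a transporters in the Impact comparison and the histone genes fall outside the rule and were chosen after their values were seen. Some genes taken by the rule are not reported here.

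Replicate numbers come from the labels, but nothing in the labels ties same-numbered samples to an animal or states that the regions come from separate mice. The p-values therefore measure the spread between these samples, and regions may share animals. Whether same-numbered samples deviated together from their group means was checked before any fit with a replicate block was examined. In primary neurons every same-numbered pair correlated between 0.334 and 0.6, and in pituitary between 0.179 and 0.186, so the numbers were taken to pair these samples, and blocked values stand beside results that they change. No pair of libraries within a group was identical or within sampling noise (lowest chi-square per degree of freedom 3.62).

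The alternatives tried were DESeq2 1.42.0, another scaling, no filter on low counts, a replicate block, gene list tests with other assumptions, leaving out each library, and leaving out Rn45s and Lars2, whose tags hold ribosomal RNA. A further alternative in TRAP was a term for sex. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.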

Results

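The data cover 62 libraries of bulk or ribosome-bound mouse RNA. Total tags, in megatags (M), ran from 17.3 to 22.8 M in hypothalamus, 15.4 to 21.8 M in periaqueductal gray, 18.5 to 23.0 M in caudate putamen and 17.3 to 24.3 M in substantia nigra. They ran from 2.24 to 3.10 M in pituitary, 7.38 to 25.4 M in P0 TRAP and 20.9 to 29.5 M in primary neurons. The ribosomal RNA gene Rn45s took 0.472 to 1.89% of tags in the brain regions, 5.30 to 8.40% in primary neurons, 13.8 to 25.6% in TRAP and 15.4 to 40.8% in pituitary. The labels of caudate putamen cKO 1 conflict, since its title names the periaqueductal gray and its tissue tag the caudate putamen. The tissue tag was used, and this library held 192 CPM of the dopamine receptor gene Drd1a, beside 186 to 207 CPM in the other caudate putamen cKO libraries and 1.37 to 2.76 CPM in periaqueductal gray cKO.

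Nova1 (Entrez 664883, GRCm38 chromosome 12, 46694517 to 46818929, minus strand) was measured in every sample as a check of the labels. It was lower in cKO by a log2 fold change of -1.86 in caudate putamen (SE 0.14, adjusted p = 2.77e-06), where it went from 52.1 ± 3.26 to 14.3 ± 4.07 CPM. In substantia nigra it fell from 88.6 ± 1.95 to 40.3 ± 9.78 CPM (-1.14, SE 0.13, adjusted p = 0.000416), and in hypothalamus from 117 ± 7.24 to 76.8 ± 17.7 CPM (-0.61, SE 0.11, adjusted p = 0.00236). In periaqueductal gray the levels were 193 ± 14.8 and 157 ± 33.4 CPM (-0.30, SE 0.11, adjusted p = 0.114), and the highest cKO library (184 CPM) lay above the lowest cHet library (182 CPM). The 4 region effects differed from each other (interaction adjusted p = 0.00144). Pituitary held little Nova1 (9.15 ± 0.982 and 5.02 ± 1.14 CPM, n = 3 each, adjusted p = 0.761). Ribosome-bound Nova1 RNA at P0 fell from 106 ± 9.33 to 13.4 ± 2.61 CPM (-3.03, SE 0.11, n = 6 each, adjusted p = 3.97e-14). In primary neurons Nova1 was at 207 ± 10.1 CPM in WT, 17.0 ± 2.18 in KO and 24.6 ± 2.06 in KO with Impact (n = 4 each), and KO differed from WT by -3.60 (SE 0.08, adjusted p = 3.94e-14).

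Impact (Entrez 16210, GRCm38 chromosome 18, 12955852 to 12992950, plus strand) fell with Nova1 in 3 settings. Ribosome-bound Impact RNA went from 32.3 ± 4.26 CPM in cHet to 17.5 ± 1.54 CPM in cKO (log2 fold change -0.87, SE 0.09, adjusted p = 3.91e-05). In primary neurons it went from 319 ± 28.5 CPM in WT to 189 ± 25.1 CPM in KO (-0.75, SE 0.09, adjusted p = 0.00038), and in substantia nigra from 410 ± 40.5 to 315 ± 32.5 CPM (-0.38, SE 0.09, adjusted p = 0.0145). The log2 fold change was -0.05 in hypothalamus (adjusted p = 0.476), -0.12 in periaqueductal gray (0.251), -0.13 in caudate putamen (0.148) and -0.02 in pituitary (0.995). The interaction of region and genotype for Impact did not pass (adjusted p = 0.309), so the 4 brain regions were not shown to differ.

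**Figure D1:**
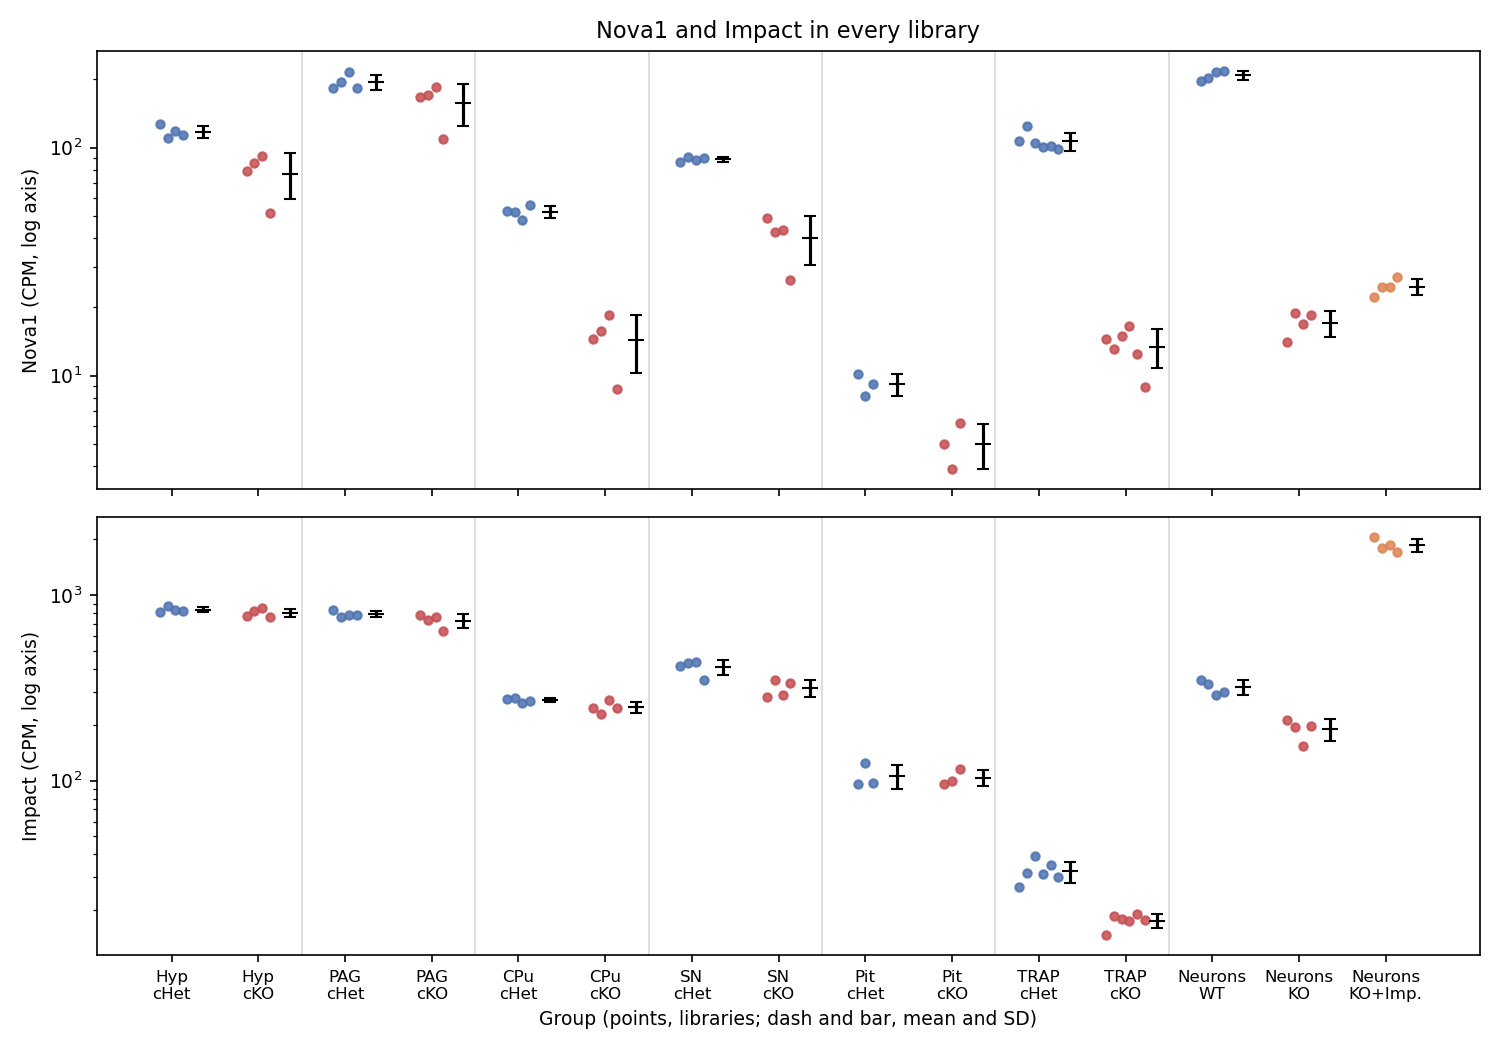
Nova1 (upper panel) and Impact (lower panel) in CPM on a log axis for each of the 62 libraries, by group; points are libraries, and the dash and bar are the group mean and SD. Nova1 in TRAP averages 106 CPM in cHet and 13.4 CPM in cKO, and Impact in primary neurons averages 319 CPM in WT, 189 CPM in KO and 1864 CPM after Impact was added.

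In the hypothalamus, 847 of 15207 tested genes rose and 976 fell in cKO against cHet (n = 4 each), with a median size of 0.32 log2 units. Rbm3 (Entrez 19652), a gene of a cold-inducible RNA-binding protein, rose from 42.9 ± 4.70 to 132 ± 15.3 CPM (log2 fold change 1.62, SE 0.08, adjusted p = 1.01e-09). Slc2a4, the insulin-responsive glucose transporter GLUT4, rose from 3.89 ± 0.635 to 12.9 ± 2.98 CPM (1.72, SE 0.17, adjusted p = 1.53e-05). Nova2, the paralog of Nova1, rose from 99.9 ± 4.22 to 120 ± 5.05 CPM (0.27, SE 0.05). The feeding peptide gene Npy rose by 0.74 (SE 0.10, adjusted p = 0.00019) and Agrp by 0.82 (SE 0.18, adjusted p = 0.00587), while Pomc, the precursor of melanocortins, fell by 0.78 (SE 0.18, adjusted p = 0.00908). The water channel gene Aqp4 of astrocyte endfeet fell by 0.67 (adjusted p = 2.45e-05), and Dock5, which activates Rac, by 1.23 (adjusted p = 2.45e-05).

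Among 44 measured neuropeptide genes, 11 rose, 1 fell and 32 did not pass (15 and 4 adjusted over the list alone). Penk, the enkephalin precursor (0.38), and Nucb2, the nesfatin precursor (0.38), rose, and the list ranked higher (adjusted p = 0.0013; adjusted p = 0.263 with an estimated correlation). Sst rose by 0.23 (adjusted p = 0.0334) and lost the call without cHet 2, cKO 3, cHet 3 or cHet 4 (adjusted p up to 0.108). Trh (0.25, adjusted p = 0.0546), Avp (-0.57, 0.103), Oxt (-0.37, 0.0782), Hcrt (-0.33, 0.197), Pmch (0.10, 0.503), Crh (0.08, 0.847) and Ghrh (0.27, 0.259) did not pass. Calls were gained by Trh without cKO 1 or cHet 2, Avp without cHet 3, Oxt without cKO 3, cHet 3 or cKO 4, and Hcrt without cKO 3. Of 24 cholesterol synthesis genes, 16 fell and 8 did not pass (19 fell and 1 rose adjusted over the list alone). They include Sc4mol (-0.63, SE 0.08), Hmgcs1 (-0.42, SE 0.05) and the sterol regulator Srebf2 (-0.35, SE 0.05), with adjusted p = 6.58e-09 for the list and adjusted p = 0.224 with an estimated correlation. Of 22 genes of the unfolded protein response, 11 fell (12 adjusted over the list alone), among them the chaperones Calr (-0.38) and Hsp90b1 (-0.30) (adjusted p = 0.000361; adjusted p = 0.49 with an estimated correlation).

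Markers of other cells also moved in hypothalamus. Of 25 oligodendrocyte genes 12 fell and 13 did not pass (17 fell adjusted over the list alone; adjusted p = 2.47e-06; adjusted p = 0.718 with an estimated correlation). They include the myelin gene Mobp, from 1793 ± 131 to 1229 ± 254 CPM, and the iron carrier Trf, from 690 ± 80.5 to 373 ± 81.6 CPM. Of 22 endothelial and pericyte genes 9 fell (13 adjusted over the list alone), such as Rgs5 (-0.73) and the VEGF receptor gene Kdr (-0.55), with adjusted p = 1.64e-07 and adjusted p = 0.224 with an estimated correlation. Of 19 fibroblast and smooth muscle genes 6 fell (12 adjusted over the list alone), such as Fn1 (-0.85; adjusted p = 0.000361 for the list; adjusted p = 0.718 with an estimated correlation). Of 6 erythroid genes 5 fell (5 adjusted over the list alone), such as Hbb-b1 (-0.71), with adjusted p = 0.00233 and adjusted p = 0.463 with an estimated correlation. Of 77 ribosomal protein genes 13 rose and 64 did not pass (14 rose adjusted over the list alone), such as Rps14 (0.32; adjusted p = 1.59e-05 for the list; adjusted p = 0.62 with an estimated correlation). Of 31 genes of GABAergic identity 4 rose and 1 fell (4 and 1 adjusted over the list alone). The vesicular transporter Slc32a1 fell by 0.24, and the list ranked higher (adjusted p = 0.00179; adjusted p = 0.224 with an estimated correlation). Of 32 cell cycle genes 5 fell (5 adjusted over the list alone), such as Top2a (-0.77), with adjusted p = 0.0222 and adjusted p = 0.224 with an estimated correlation. This last call was lost without cKO 3 (adjusted p = 0.0568) or cKO 4 (adjusted p = 0.0708). The count of changed genes was 1060 without cKO 1 and 1169 without cKO 2.

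In the periaqueductal gray, 649 of 14980 genes rose and 809 fell in cKO (n = 4 each; median size 0.377 log2 units), although Nova1 itself did not pass. Rbm3 rose from 40.4 ± 6.25 to 120 ± 14.8 CPM (log2 fold change 1.56, SE 0.10, adjusted p = 2.25e-07). Otoa, which codes for the inner ear protein otoancorin, rose from 2.43 ± 0.745 to 9.79 ± 2.68 CPM (1.99, SE 0.23, adjusted p = 0.000112). Npy rose from 6.72 ± 2.86 to 19.5 ± 5.82 CPM (1.52, SE 0.25, adjusted p = 0.00153). Nova2 rose by 0.47 (SE 0.07, adjusted p = 0.00103) and the apoptosis gene Hrk by 0.85. The glycine receptor gene Glra1 fell by 0.50 (SE 0.09, adjusted p = 0.00231), and the synaptic vesicle gene Syt2 by 0.52 (SE 0.10, adjusted p = 0.00284).

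Of 33 measured neuropeptide genes in periaqueductal gray, 5 rose and 28 did not pass (5 adjusted over the list alone), among them Sst (0.45) and the peptide-processing gene Cpe (0.31; adjusted p = 0.00276 for the list; adjusted p = 0.586 with an estimated correlation). Of 21 genes of GABAergic identity 5 rose and 1 fell (12 and 1 adjusted over the list alone), such as Calb2 (0.33), with adjusted p = 0.000223 and adjusted p = 0.142 with an estimated correlation. The transmitter genes Tph2 (-0.62, adjusted p = 0.387), Tac1 (0.16, 0.321), Penk (0.25, 0.0799), Gad2 (0.21, 0.0531) and Slc17a6 (-0.12, 0.207) did not pass. Tph2 gained a call without cKO 1, Penk without cHet 1 or cKO 3, and Gad2 without cKO 1 or cHet 4. Of 24 cholesterol synthesis genes 16 fell (20 adjusted over the list alone), such as Hmgcs1 (-0.43, SE 0.06), with adjusted p = 1.16e-09 and adjusted p = 0.28 with an estimated correlation. Of 22 genes of the unfolded protein response 8 fell (9 adjusted over the list alone), such as Hspa5 (-0.34; adjusted p = 0.00127 for the list; adjusted p = 0.586 with an estimated correlation).

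In the same tissue, 8 of 25 oligodendrocyte genes fell (9 fell and 1 rose adjusted over the list alone), such as Trf (-0.85; adjusted p = 0.00377 for the list; adjusted p = 0.878 with an estimated correlation). Of 22 endothelial and pericyte genes 5 fell (13 adjusted over the list alone), such as Tie1 (-0.80), with adjusted p = 1.18e-05 and adjusted p = 0.586 with an estimated correlation. Of 7 erythroid genes 4 fell (5 adjusted over the list alone), such as Hbb-b1 (-0.74), with adjusted p = 0.00455 and adjusted p = 0.586 with an estimated correlation. A list of 12 genes first chosen for pituitary stem and folliculostellate cells had 5 that rose (6 adjusted over the list alone), such as the astrocyte glutamate transporter Slc1a3 (0.43). This list ranked higher (adjusted p = 0.0178; adjusted p = 0.28 with an estimated correlation). Of 77 ribosomal protein genes 3 rose (2 adjusted over the list alone), including Rpl5 (0.55; adjusted p = 0.00272 for the list; adjusted p = 0.944 with an estimated correlation). Of 76 respiratory chain genes 3 fell (3 adjusted over the list alone), such as Atp5j2 (-0.33), with adjusted p = 0.0401 and adjusted p = 0.944 with an estimated correlation. The pituitary stem call was lost without cKO 4 (adjusted p = 0.0638), and the ribosomal call without cKO 1 (0.1) or cHet 3 (0.0976). The respiratory call was lost without cHet 1 (adjusted p = 0.141), cHet 2 (0.0506), cKO 3 (0.667) or cHet 4 (0.0821). The count of changed genes was 901 without cKO 1, 764 without cKO 2 and 913 without cHet 2.

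In the caudate putamen, 799 of 15017 genes rose and 760 fell in cKO (n = 4 each; median size 0.357 log2 units). Rbm3 rose from 48.1 ± 3.0 to 139 ± 14.8 CPM (log2 fold change 1.53, SE 0.08, adjusted p = 6.48e-09). Lgals3bp, a secreted glycoprotein gene, rose from 18.9 ± 2.36 to 44.2 ± 5.64 CPM (1.22, SE 0.10, adjusted p = 7.34e-06). The activity-regulated gene Arc fell from 95.9 ± 33.7 to 33.3 ± 3.31 CPM (-1.53, SE 0.18, adjusted p = 0.000226). Of 33 interferon response genes, 20 rose and 13 did not pass (26 rose adjusted over the list alone; adjusted p = 4.37e-12; adjusted p = 0.751 with an estimated correlation). They include the transcription factor gene Irf7 (1.66, SE 0.32), Ifit3 (1.79, SE 0.35), Oasl2 (1.80, SE 0.32) and the antiviral gene Mx1 (2.21, SE 0.45).

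The mean log2 CPM of the interferon list lay between 2.26 and 3.43 in caudate putamen cKO and between 1.70 and 2.18 in cHet (exact permutation p = 0.0286, two-sided, 70 assignments; 0.114 adjusted over the 4 regions). The same test gave exact p = 0.6 in hypothalamus, 0.514 in periaqueductal gray and 0.771 in substantia nigra. In those regions 1 rose and 1 fell of 29, 0 of 31 changed and 1 of 32 rose, and the list was not called (adjusted p = 0.0968, 0.218 and 0.424). The change in caudate putamen exceeded the mean of the others by 0.727 log2 units. A permutation test of the labels within each region gave p = 0.13 (two-sided, 1e+05 permutations). Splitting the replicate numbers together in all regions gave 1 of 35, the real split (permutation p = 0.0286), and both tests were chosen after the result was seen.

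**Figure D2:**
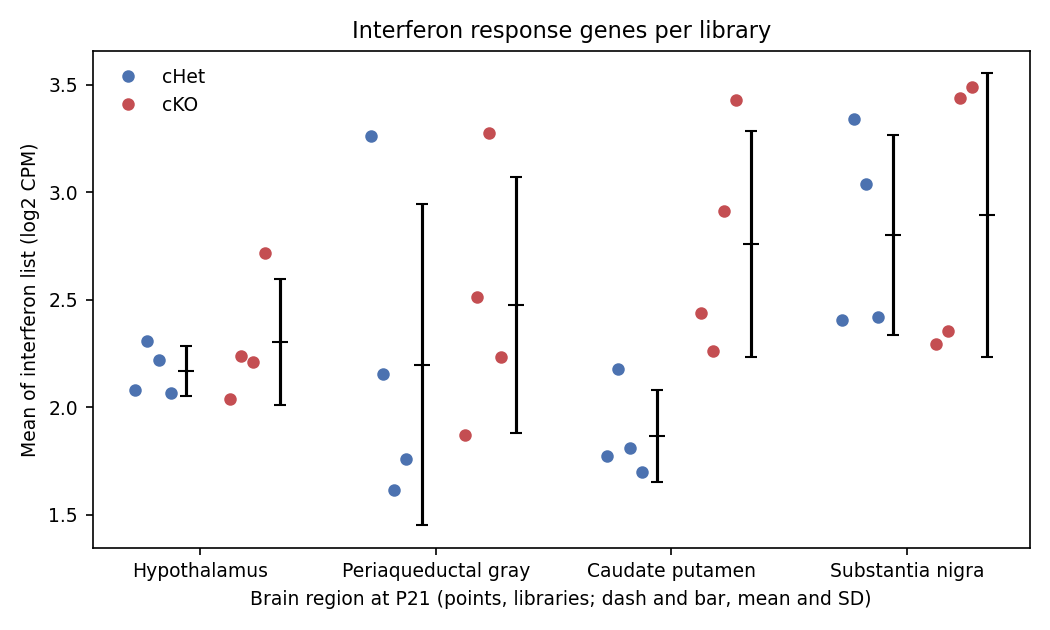
Mean log2 CPM of the interferon response genes in each library of the 4 brain regions at P21, cHet in blue and cKO in red; points are libraries, and the dash and bar are the group mean and SD. In caudate putamen the cKO libraries lie between 2.26 and 3.43 and the cHet libraries between 1.70 and 2.18.

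Among 30 genes of striatal projection neurons in caudate putamen, 5 fell, 1 rose and 24 did not pass (7 and 1 adjusted over the list alone), with adjusted p = 0.00868 and adjusted p = 0.788 with an estimated correlation. The adenylate cyclase gene Adcy5 fell by 0.25, and Ppp1r1b, which codes for DARPP-32, rose by 0.27. The dopamine receptor genes Drd1a (-0.03, adjusted p = 0.775) and Drd2 (-0.11, 0.233) and the peptide genes Penk (-0.05, 0.638) and Tac1 (0.02, 0.856) did not pass. Of 31 genes of GABAergic identity 5 rose and 1 fell (6 and 1 adjusted over the list alone), such as Sst (0.36; adjusted p = 0.00868 for the list; adjusted p = 0.751 with an estimated correlation). Of 24 cholesterol synthesis genes 10 fell (14 adjusted over the list alone), such as Cyp51 (-0.36), with adjusted p = 0.000413 and adjusted p = 0.751 with an estimated correlation. Of 22 genes of the unfolded protein response 8 fell (13 fell and 1 rose adjusted over the list alone), such as its transcription factor Xbp1 (-0.54; adjusted p = 0.00173 for the list; adjusted p = 0.751 with an estimated correlation). Of 22 endothelial and pericyte genes 5 fell (10 adjusted over the list alone), such as Rgs5 (-0.79), with adjusted p = 0.0013 and adjusted p = 0.751 with an estimated correlation. The complement gene C4b (0.83, SE 0.09) and Agt, an astrocyte gene for angiotensinogen (0.76, SE 0.10), also rose. The GABAergic call was lost without cKO 4 (adjusted p = 0.0548) and the striatal call without cHet 3 (0.143). The count of changed genes was 1018 without cHet 1, 826 without cKO 2, 902 without cHet 2, 890 without cHet 3 and 931 without cHet 4.

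In the substantia nigra, 646 of 14858 genes rose and 811 fell in cKO (n = 4 each; median size 0.399 log2 units). Rbm3 rose from 43.9 ± 6.2 to 133 ± 25.1 CPM (log2 fold change 1.60, SE 0.13, adjusted p = 4.94e-05). The sodium channel subunit gene Scn4b fell from 69.0 ± 6.65 to 35.0 ± 3.79 CPM (-0.98, SE 0.09, adjusted p = 0.000178). The calcium buffer gene Pvalb fell from 174 ± 22.9 to 126 ± 18.3 CPM (-0.48, SE 0.10, adjusted p = 0.0131). The potassium channel gene Kcna6 (-0.60) and the pacemaker channel gene Hcn2 (-0.52) also fell, while Calb2 (0.57) and Penk (0.82) rose. The dopaminergic genes Th (-0.00, SE 0.10, adjusted p = 0.992) and Slc6a3 (-0.09, SE 0.11, adjusted p = 0.658) and the GABA synthesis genes Gad1 (0.04, adjusted p = 0.761) and Gad2 (0.00, adjusted p = 0.996) did not pass.

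Of 31 voltage-gated sodium and potassium channel genes in substantia nigra 7 fell and 2 rose (9 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.0859). Of 23 cholesterol synthesis genes 15 fell (19 adjusted over the list alone), such as Dhcr7 (-0.54), with adjusted p = 2.26e-08 and adjusted p = 0.821 with an estimated correlation. Of 22 genes of the unfolded protein response 8 fell (10 fell and 1 rose adjusted over the list alone), such as Pdia4 (-0.47; adjusted p = 0.000713 for the list; adjusted p = 0.821 with an estimated correlation). Of 25 oligodendrocyte genes 7 fell (10 adjusted over the list alone), with adjusted p = 0.000789 and adjusted p = 0.821 with an estimated correlation. Of 22 endothelial and pericyte genes 7 fell (12 adjusted over the list alone), such as the VEGF receptor gene Flt1 (-0.52), with adjusted p = 9.62e-07 and adjusted p = 0.377 with an estimated correlation. Of 19 fibroblast genes 4 fell (5 fell and 1 rose adjusted over the list alone), such as Col1a1 (-0.63; adjusted p = 0.00522 for the list; adjusted p = 0.821 with an estimated correlation). Of 7 erythroid genes 2 fell (4 adjusted over the list alone), such as Hbb-b1 (-0.76), with adjusted p = 0.0366 and adjusted p = 0.821 with an estimated correlation. Of 77 ribosomal protein genes 5 rose (5 adjusted over the list alone), such as Rpl5 (0.52; adjusted p = 7.71e-05 for the list; adjusted p = 0.821 with an estimated correlation). The fibroblast call was lost without cHet 2 (adjusted p = 0.0838) or cKO 4 (0.0735), and the erythroid call without cHet 1 (0.0943), cHet 2 (0.0534), cHet 3 (0.0554) or cKO 4 (0.106). The count of changed genes was 779 without cKO 1, 744 without cHet 1, 705 without cKO 2 and 921 without cHet 2.

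The 4 brain regions shared many changed genes. Of 14227 genes tested in each, 107 rose and 180 fell in all 4, where independent lists would give 0.0876 and 0.158. In at least 1 region 1748 rose and 1840 fell, and 11 genes rose in some region and fell in another. Agt rose by 0.45, 0.66, 0.76 and 0.49 in hypothalamus, periaqueductal gray, caudate putamen and substantia nigra. The cold-inducible gene Cirbp rose by 1.02, 0.95, 1.24 and 1.16 in the same order, and the heat shock gene Hsph1 fell by 0.93, 0.91, 0.71 and 1.00 (adjusted p = 1.53e-05, 1.86e-05, 0.000164 and 0.000423). Across genes, which are not independent replicates, log2 fold changes of region pairs correlated between 0.509 and 0.627 (Pearson; Spearman 0.506 to 0.643). Hypothalamus and periaqueductal gray shared 347 genes that rose (36.4 for independent lists) and 482 that fell (52.8), and caudate putamen and substantia nigra, the pair with the fewest, 206 (34.0) and 275 (41.2). Since the regions may come from the same mice, these values do not stand for independent animals.

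In the joint fit of the 4 regions, 3081 of 16042 genes rose on average and 3147 fell. This count of 6228 ran from 4804 to 6454 over the other settings, among them a random block by replicate number. The effect of genotype differed between regions for 51 genes, and Pde2a, a cyclic nucleotide phosphodiesterase gene, had the smallest adjusted p (0.000443). Its log2 fold changes were 0.02 in hypothalamus, -0.26 in periaqueductal gray, -0.15 in caudate putamen and 0.43 in substantia nigra. Dgkg, a diacylglycerol kinase gene, had values of -0.08, -0.18, -0.14 and -0.95 in the same order (adjusted p = 0.000897). Synpr, a synaptic vesicle gene, had values of 0.37, 0.38, -0.23 and 0.55 (adjusted p = 0.00144). The count of 51 was 77 without periaqueductal gray cKO 1, 31 without caudate putamen cKO 1, 26 without caudate putamen cHet 1, 26 without caudate putamen cKO 2 and 29 without caudate putamen cHet 2. It was 28 without substantia nigra cHet 1 and 31 without substantia nigra cKO 2. The joint fit treats the 32 libraries as independent, and with the replicate number as a random block 151 genes passed, 50 of them among the 51.

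In the pituitary, 1 of 12265 genes changed between cKO and cHet (n = 3 each). An unadjusted p under 0.05 was held by 803 genes, where chance gives about 613, and DESeq2 called 5. Lhb, the luteinizing hormone beta subunit gene (Entrez 16866), fell from 222 ± 37.5 to 68.3 ± 28.2 CPM (log2 fold change -1.70, SE 0.22, adjusted p = 0.00411). With a replicate block 33 genes changed, 16 up and 17 down. They include Lhb (-1.74, adjusted p = 7.45e-07), Fshb, the follicle-stimulating hormone beta subunit gene (-1.40, adjusted p = 0.000455), and the growth hormone gene Gh (-0.45, adjusted p = 0.0257). Without the block the values were -1.20 for Fshb (SE 0.33, adjusted p = 0.457) and -0.45 for Gh (adjusted p = 0.718), and Fshb passed without cKO 2. Prl (-0.39, adjusted p = 0.841), Cga (-0.38, 0.749), Pomc (0.22, 0.918) and Tshb (0.69, 0.731) did not pass. The Lhb call was lost without cHet 2 (adjusted p = 0.0692) or cKO 3 (0.0625). The count of changed genes was 4 without cKO 1, 0 without cHet 2, 9 without cKO 2, 2 without cHet 3 and 0 without cKO 3.

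Lists with a call in pituitary held no member that passed over all genes. The oligodendrocyte list ranked lower (0 of 13 changed, 3 fell adjusted over the list alone; adjusted p = 0.00672; adjusted p = 0.884 with an estimated correlation). The synaptic vesicle list did as well (0 of 30 changed, 2 fell adjusted over the list alone; adjusted p = 0.00672; adjusted p = 0.884 with an estimated correlation). The respiratory chain list ranked lower (0 of 76, and 0 adjusted over the list alone; adjusted p = 0.0109; adjusted p = 0.884 with an estimated correlation). The fibroblast list ranked higher (0 of 15, 4 rose adjusted over the list alone; adjusted p = 0.0186; adjusted p = 0.884 with an estimated correlation). Of 35 genes of pituitary hormones and cell types 1 fell, Lhb (2 adjusted over the list alone), and the list was not called (adjusted p = 0.447). Rn45s took 15.4 to 32.6% of tags in cKO and 25.6 to 40.8% in cHet, so this sign of ribosomal RNA carry-over moved with genotype. The oligodendrocyte call was lost without cHet 1 (adjusted p = 0.191), and the fibroblast call without cKO 1 (0.66), cHet 2 (0.0659) or cHet 3 (0.0502). The synaptic call was lost without cHet 1 (0.0514), cKO 1 (0.102) or cHet 2 (0.0659), and the respiratory call without cHet 1 (0.265), cKO 2 (0.136) or cHet 3 (0.364).

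In ribosome-bound RNA of P0 brain, 0 of 13009 genes rose and 4 fell in cKO (n = 6 each). The 4 were Nova1, Impact, Dzip1 and Ahi1. An unadjusted p under 0.05 was held by 966 genes, where chance gives about 650, and DESeq2 called 3 up and 13 down. Dzip1, a gene of primary cilium formation, fell from 251 ± 8.75 to 189 ± 10.5 CPM (log2 fold change -0.41, SE 0.05, adjusted p = 0.000192). Ahi1, a gene of the ciliary transition zone, fell from 416 ± 10.6 to 322 ± 26.4 CPM (-0.37, SE 0.05, adjusted p = 0.00321). All 4 calls held when any of the 12 libraries was left out. The inhibitory neuron genes Gad1 (-0.10, adjusted p = 0.718), Gad2 (-0.23, 0.598), Slc32a1 (-0.19, 0.571), Sst (-0.05, 0.904) and Dlx1 (-0.05, 0.878) did not pass. Gad2 levels did not overlap, at 310 ± 11 CPM in cHet and 264 ± 37.4 CPM in cKO.

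In TRAP the integrated stress response list, genes driven by ATF4, ranked lower (0 of 43 changed, and 0 adjusted over the list alone; adjusted p = 0.0362; adjusted p = 0.885 with an estimated correlation). The axon guidance list also ranked lower (0 of 39, and 0 adjusted over the list alone; adjusted p = 0.0362; adjusted p = 0.885 with an estimated correlation). The stress response call was lost without cKO 1 (adjusted p = 0.22), cKO 4 (0.0589), cKO 5 (0.0705), cHet 2 (0.123), cHet 4 (0.0556) or cHet 6 (0.0784). The axon guidance call was lost without cKO 1 (0.492), cKO 4 (0.065), cHet 3 (0.129) or cHet 4 (0.0869). Across genes, TRAP and region fold changes correlated between -0.0129 and 0.0848. Of the 4 genes that fell in TRAP, 2 fell in hypothalamus (0.269 for independent lists, Fisher's exact adjusted p = 0.035) and 2 in caudate putamen (adjusted p = 0.0241). Of the same genes, 3 fell in substantia nigra (0.231 for independent lists, adjusted p = 0.00126) and 0 in periaqueductal gray (adjusted p = 1). With Nova1 left out, 1 of 3 fell in hypothalamus (adjusted p = 0.252), 1 in caudate putamen (adjusted p = 0.216) and 2 in substantia nigra (adjusted p = 0.0153). With adjusted p under 0.10 as the threshold in both lists, the overlap had adjusted p = 0.0661 in hypothalamus and 0.0586 in caudate putamen. Dzip1 fell in hypothalamus (-0.29, adjusted p = 0.00109), caudate putamen (-0.48, 0.0027) and substantia nigra (-0.38, 0.00711), and its value in periaqueductal gray was -0.17 (0.0626).

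In primary neurons, Cre was used to remove Nova1 in culture. Of 14829 genes 31 rose and 76 fell in KO against WT (n = 4 each). Beside Nova1 and Impact, Nova2 rose from 166 ± 6.95 to 235 ± 6.13 CPM (log2 fold change 0.50, SE 0.04, adjusted p = 1.08e-05). The noncoding gene Gt(ROSA)26Sor rose from 2.60 ± 0.489 to 14.8 ± 1.72 CPM (2.50, SE 0.13, adjusted p = 1.12e-08). It stood at 14.7 ± 1.16 CPM in KO with Impact. WT received no Cre, so comparisons with WT cannot tell loss of Nova1 from an effect of Cre itself. Itpr1, a calcium release channel gene, fell from 84.3 ± 10.1 to 52.3 ± 3.72 CPM (-0.69, SE 0.08, adjusted p = 0.00038). The BMP receptor gene Bmpr1b fell by 0.82 (SE 0.11, adjusted p = 0.0023), and Rdh5, a retinol dehydrogenase gene, by 0.90 (SE 0.10, adjusted p = 0.00038). Mapt, the gene of tau, rose by 0.35 (SE 0.06, adjusted p = 0.0112), and the imprinted gene Peg10 by 0.39 (SE 0.07, adjusted p = 0.0112). With a replicate block 942 genes changed, 452 up and 490 down, among them all 107. The count of 107 was 50 without WT 1, 52 without KO 1, 52 without KO 2, 59 without KO 3 and 46 without WT 4.

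The camera test called 14 of 33 lists in KO against WT, 11 higher and 3 lower, and 5 of these calls held when any library was left out. Of 24 cholesterol synthesis genes 2 rose (3 adjusted over the list alone; list adjusted p = 1.61e-05; adjusted p = 0.456 with an estimated correlation). Of 21 astrocyte genes 2 fell, the connexin gene Gja1 (-0.46) and Clu (-0.30; 6 fell and 1 rose adjusted over the list alone; list adjusted p = 0.000162; adjusted p = 0.233 with an estimated correlation). Of 28 striatal genes 1 rose (1 adjusted over the list alone; adjusted p = 0.012; adjusted p = 0.215 with an estimated correlation). Neuropeptide genes ranked higher (0 of 32 changed, 3 rose adjusted over the list alone; adjusted p = 0.000162; adjusted p = 0.456 with an estimated correlation, and 0.0177 with block and estimated correlation together). Pituitary hormone and cell type genes also ranked higher (0 of 22 changed, and 0 adjusted over the list alone; adjusted p = 0.000226; adjusted p = 0.215 with an estimated correlation, and 0.0177 with block and estimated correlation together). The block raised the lists called from 14 to 16, and 2 of these passed with an estimated correlation. These 2, the neuropeptide and the pituitary list, both name Pomc, Pcsk1, Pcsk2, Chgb and Scg2. Their calls are therefore not independent, here or in the other neuron comparisons. Of 4 genes that fell in TRAP, 3 fell in KO neurons, namely Nova1, Impact and Ahi1 (-0.23, adjusted p = 0.0226), where independent lists give 0.0223 (Fisher's exact adjusted p = 1.23e-06; 0.000165 with Nova1 left out). Hypothalamus shared 7 genes that rose (1.79 for independent lists, adjusted p = 0.00259) and 9 that fell (4.80, adjusted p = 0.0752). With adjusted p under 0.10 as the threshold in both lists, these were 14 (6.23, adjusted p = 0.00676) and 26 (11.4, adjusted p = 9.93e-05).

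Among 50 integrated stress response genes, 1 fell in KO against WT, the cystine transporter Slc7a11 (-0.59, adjusted p = 0.00547; 1 adjusted over the list alone), and the list was not called (adjusted p = 0.167). Atf4, the transcription factor of this response, was at 112 ± 14.8 CPM in WT and 123 ± 14.4 in KO (log2 fold change 0.14, SE 0.09, adjusted p = 0.634; 0.0379 with a replicate block). Ddit3 (-0.20, adjusted p = 0.696), Trib3 (-0.30, 0.766), Asns (0.09, 0.624) and Chac1 (0.01, 0.993) did not pass. Of 22 genes of GCN2, eIF2 and eIF2B 1 fell, Impact (1 adjusted over the list alone), and the list was not called (adjusted p = 0.639).

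In KO neurons, the Impact vector raised Impact RNA from 189 ± 25.1 to 1864 ± 156 CPM (log2 fold change 3.30, SE 0.09, adjusted p = 1.04e-12). This was the 1 gene that changed against KO (n = 4 each). An unadjusted p under 0.05 was held by 461 genes, fewer than the 741 that chance gives, and DESeq2 called 8. Integrated stress response genes ranked lower (0 of 50 changed, 4 fell adjusted over the list alone; adjusted p = 6.57e-11; adjusted p = 0.641 with an estimated correlation), with a median log2 fold change of -0.0979. Their values include -0.24 for Atf4 (SE 0.09, adjusted p = 1) and -0.25 for Asns, asparagine synthetase (SE 0.06, adjusted p = 1), while Chac1 (-0.34), Trib3 (-0.08) and Ddit3 (0.04) had adjusted p = 1. With a replicate block 27 genes changed, 12 up and 15 down. Atf4 (-0.23, adjusted p = 0.00795) and Asns (-0.25, 0.0011) passed in that fit, as did the amino acid transporters Slc7a1 (-0.27, 0.000998), Slc7a3 (-0.38, 0.0011) and Slc7a5 (-0.23, 0.0148). The stress response list had adjusted p = 2.25e-13 with the block and 0.158 with block and estimated correlation together. Nova1 itself was 0.53 higher (SE 0.08, adjusted p = 0.0666; 6.26e-05 with the block) and passed without KOImpact 1 (0.0486) or KO 2 (0.0359). The count of changed genes was 2 without KOImpact 1 and 3 without KO 2, where Slc7a3 passed.

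Of 20 reactive gliosis genes 0 changed (1 rose adjusted over the list alone), and the list ranked higher after Impact was added (adjusted p = 0.0016; adjusted p = 0.641 with an estimated correlation). Gfap (0.60, adjusted p = 1) and Serpina3n (0.66, adjusted p = 0.498) passed with the block (0.58, adjusted p = 0.000383, and 0.66, adjusted p = 0.00795). Astrocyte genes ranked higher (0 of 21, and 0 adjusted over the list alone; adjusted p = 0.0129; adjusted p = 0.641 with an estimated correlation). Ribosomal protein genes ranked lower (0 of 77, 1 fell adjusted over the list alone; adjusted p = 9.39e-08; adjusted p = 0.679 with an estimated correlation). Respiratory chain genes did as well (0 of 76, and 0 adjusted over the list alone; adjusted p = 1.87e-07; adjusted p = 0.679 with an estimated correlation). The gliosis call was lost without KOImpact 2 (adjusted p = 0.0603) and the astrocyte call without KOImpact 2 (0.108), KO 3 (0.219) or KOImpact 4 (0.0736). The block raised the lists called from 5 to 9, the neuropeptide list (lower, adjusted p = 0.00488) and the pituitary hormone list (lower, 0.0213) among them. With block and estimated correlation together these had adjusted p = 0.158 and 0.169, and 0 lists passed.

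Against WT, KO neurons with Impact had 18 genes that rose and 38 that fell (n = 4 each), or 211 and 292 with a replicate block, which kept all 56. Nova2 rose by 0.45 (SE 0.04, adjusted p = 3.71e-05) and Serpina3n, a reactive astrocyte gene, by 0.93 (SE 0.13, adjusted p = 0.00314). Pdgfrb, a pericyte receptor gene, fell by 1.07 (SE 0.13, adjusted p = 0.000623), and Nid1, a basement membrane gene, from 162 ± 18.4 to 103 ± 4.99 CPM (-0.65, SE 0.08, adjusted p = 0.000623). Of 50 integrated stress response genes 1 fell (15 adjusted over the list alone), Slc7a11 (-0.56, adjusted p = 0.0105; 0.0517 without KOImpact 1), and the list ranked lower (adjusted p = 2.09e-12; adjusted p = 0.399 with an estimated correlation). Of 20 reactive gliosis genes 3 rose (5 adjusted over the list alone), with adjusted p = 0.000237 and adjusted p = 0.399 with an estimated correlation. Beside Serpina3n these were Gfap and Vim. Gfap (1.51, adjusted p = 0.0197) lost its call without KOImpact 1, WT 2, KOImpact 2, WT 3 or WT 4 (up to 0.0815). Vim (0.29, adjusted p = 0.0182) lost it without WT 1, KOImpact 1, WT 2, KOImpact 2 or WT 4 (up to 0.0819). Cholesterol synthesis genes ranked higher (0 of 24 changed, 3 rose adjusted over the list alone; adjusted p = 1.57e-05; adjusted p = 0.549 with an estimated correlation). Oligodendrocyte genes ranked lower (0 of 19, and 0 adjusted over the list alone; adjusted p = 0.000549; adjusted p = 0.549 with an estimated correlation, and 0.0411 with block and estimated correlation together). Neuropeptide genes ranked higher (0 of 32, and 0 adjusted over the list alone; adjusted p = 0.0154; adjusted p = 0.687 with an estimated correlation, and 0.0411 with both). Pituitary hormone and cell type genes ranked higher as well (0 of 22, and 0 adjusted over the list alone; adjusted p = 0.0222; adjusted p = 0.549 with an estimated correlation, and 0.0411 with both). The neuropeptide call was lost without KOImpact 2 (adjusted p = 0.157) or WT 3 (0.535), and the pituitary hormone call without KOImpact 2 (0.0818), KOImpact 4 (0.0838) or WT 3 (0.225). The count of 56 was 29 without WT 1, 23 without KOImpact 1, 36 without WT 2 and 28 without KOImpact 2. It was 35 without WT 3, 31 without KOImpact 3, 22 without WT 4 and 26 without KOImpact 4. The block raised the lists called from 8 to 14, and 3 of these passed with block and estimated correlation together.

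**Figure D3:**
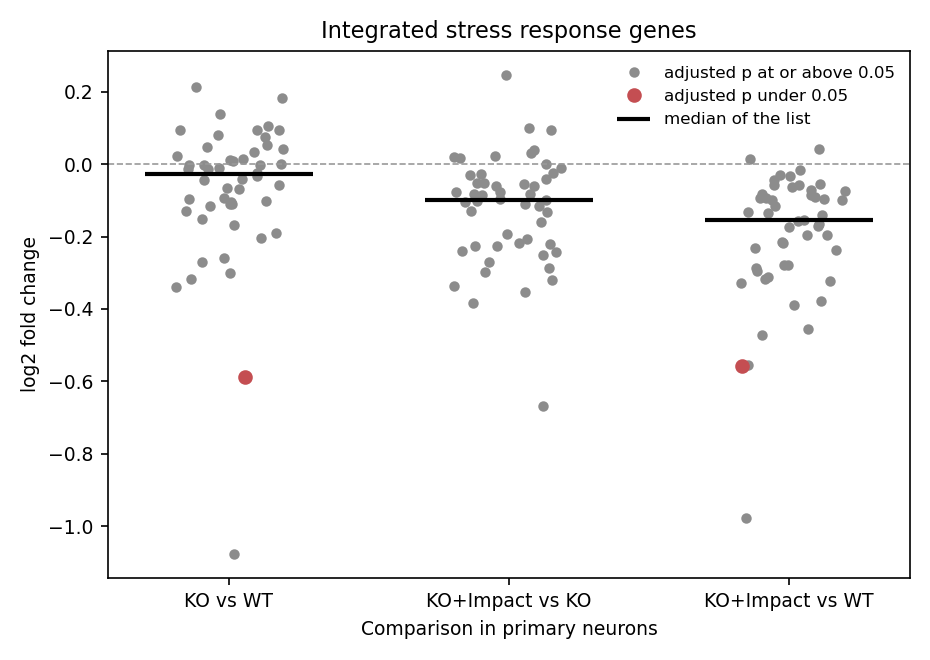
Log2 fold changes of the 50 measured integrated stress response genes in the 3 comparisons of primary neurons; each point is a gene, red points have an adjusted p under 0.05 and the line is the list median. The medians are -0.0286 for KO against WT, -0.0979 for added Impact against KO and -0.156 for added Impact against WT.

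Whether added Impact moved the genes of Nova1 loss back was measured across genes. Of the 107 genes changed in KO, Impact alone was called in the opposite direction. With a replicate block, 10 of 942 were called back and 2 were called the same way. The 10 include Impact, which the vector supplied, and Nova1, the deleted gene, and among the 8 others are Atf4, Abca1, a cholesterol export gene, and Notch1. Nova1 averaged 17.01 CPM in KO and 24.55 CPM in KO with Impact, beside 207.1 CPM in WT. For genes called back, an effect of Impact therefore cannot be told from less complete loss of Nova1. Both contrasts share the KO libraries, which alone gives opposite signs and a negative covariance. The covariance of the log2 fold changes was -0.0133 (Pearson r across genes -0.451), beside -0.0136 (SD 0.00051) in 100 simulations of unchanged groups. The simulations drew every library independently, so they leave out what cultures of the same number share and give no sound value for no reversal here. When the KO libraries were split so that no library was shared, the covariance was 0.00163 (SD 0.00242 over 6 splits, 2 of them below 0), a value that shared culture effects push upward by construction. Paired by culture number it was -0.00271 (SD 0.00263, 11 of 12 below 0), where the 12 pairs share libraries among them and no test was made. For genes with a mean log2 CPM of at least 3, the value without pairing was -0.000389 (SD 0.00131, 3 of 6 below 0) and the paired value -0.00272 (SD 0.00122, 12 of 12 below 0).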

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

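Of the tests in this part, that of the share of non-neuronal cells, that of brain tissue as the source of the Lhb difference and those on the interferon list were chosen only after the result was seen.

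In the 4 brain regions of cKO mice, Rbm3 and Cirbp were higher and Hsph1 was lower, and a lower temperature of the cKO animals or tissue is a candidate explanation. In hypothalamus, periaqueductal gray, caudate putamen and substantia nigra, 28 further heat shock genes had medians of -0.191, -0.21, -0.217 and -0.236, and 11, 11, 13 and 12 fell, with unadjusted camera p = 5.07e-07, 2.19e-07, 1.97e-06 and 2.51e-07 (p = 0.0473, 0.0392, 0.114 and 0.045 with an estimated correlation). This list was not among the 34 and was drawn up after Rbm3, Cirbp and Hsph1 had been seen in the same libraries. Its members P4ha1, Cryab and Ppid fell in all 4 regions. The list therefore shows how far the pattern reaches and is no independent support for a cause. Against a change of all non-neuronal cells alike as the whole source, the astrocyte or microglia median stood apart from the endothelial median in 4 of the 4 regions. In hypothalamus the astrocyte, microglia and endothelial medians were -0.0942, -0.09 and -0.412. A lower share of vascular cells alone would also set these medians apart, so the rule leaves such a change open. The SE behind this rule treats the genes of a list as independent and leaves out the spread between samples. Against alleles that flank Nova1, 0 of the 35 placed cold and heat shock genes lay within 10 Mb of it, and 19 of 48 tested genes in that window had changed on average, 39.6% against 38.9% elsewhere (Fisher's exact p = 1). In pituitary, which a lower animal temperature would also reach, 0 of 27 of these genes fell and 20 lay below 0. Their median was -0.0841 (unadjusted camera p = 0.135, and p = 0.693 with an estimated correlation). Pituitary Rbm3 went from 93.65 ± 33.6 CPM in cHet to 117.1 ± 12.4 CPM in cKO, and Cirbp from 98.15 ± 47.1 to 130.4 ± 40.2. Hsph1 went from 99.75 ± 42.4 to 77.36 ± 18.9 CPM. These directions are those of the brain regions, but the groups overlapped. Pituitary cannot decide on temperature, since only 10.4% of simulated 1.5-fold changes were recovered there. Hsf1, the gene of heat shock factor 1, also fell in all 4 regions. Its log2 fold changes were -0.402, -0.434, -0.447 and -0.505 in the order above. No temperature was used here, so an effect of Nova1 loss on these genes by another route stays open and untested. Whether Hsf1 is part of such a route was not tested either.

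The interferon list was higher in caudate putamen cKO (adjusted p = 4.37e-12; adjusted p = 0.751 with an estimated correlation). A single library as the source is argued against by the list means, which lay at 2.26 to 3.43 in the 4 cKO libraries and 1.70 to 2.18 in cHet, and by an adjusted p of at most 1.01e-08 with the preset correlation when any of the 8 libraries was left out. This cannot speak to a few libraries together. The means of cKO 3 (2.913) and cKO 4 (3.431) were highest, while cKO 2 (2.261) lay near cHet 2 (2.178). In other regions single cHet libraries reached 3.264 (periaqueductal gray) and 3.339 (substantia nigra). Library cKO 4 was also highest in hypothalamus (2.72) and substantia nigra (3.489), but not in periaqueductal gray (2.236). More microglia are argued against by the interferon median, which lay 0.874 log2 units above the microglia median of -0.0108. The SE of this difference (0.115) treats the genes of a list as independent and leaves out the spread between samples. It is therefore no measure of certainty here. Whether the change belongs to the caudate putamen stays open, since a permutation test within each region gave p = 0.13, and the share of 1 in 35 splits by number (0.0286) is the smallest possible and comes from a contrast chosen for this region. An infection or another exposure shared by some animals may have had the same outcome and could not be tested with the labels.

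In pituitary cKO, oligodendrocyte and synaptic genes ranked lower (adjusted p = 0.00672 each; adjusted p = 0.884 with an estimated correlation), calls that were lost without cHet 1 (0.191 and 0.0514), the synaptic one also without cKO 1 (0.102) or cHet 2 (0.0659). Brain tissue carried over into the cHet pieces is a candidate source, since 20 tested brain transcripts had a median log2 fold change of -0.152 and 15 of them (75.0%) lay below 0. Their summed level ran from 1467 to 1666 CPM in cHet and from 1269 to 1626 CPM in cKO, so the groups overlapped. It cannot explain the fall of Lhb, since brain libraries held under 1 CPM of it and dilution in cHet would raise it in cKO, whereas it was lower by a log2 fold change of -1.70 (SE 0.22). A change in the glial and nerve fibre content of the cKO pituitary stays open and was not tested.

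How often other splits of the same libraries into groups of the same sizes gave as many changed genes was counted for each comparison. Only the real split of 35 reached its count in hypothalamus (1823, highest other 0), periaqueductal gray (1458, highest other 1), caudate putamen (1559, highest other 0) and substantia nigra (1457, highest other 8). The same held for the average over regions (6228, highest other 2516) and the interaction (51, highest other 0). In each this is 1 of 35, a share under 0.05 but the smallest that 35 splits can give. For the average and the interaction, the replicate numbers were split together in all 4 regions, and no label ties a number to an animal. In TRAP 2 of 100 splits drawn gave at least 4 genes, a share under 0.05, but the other split gave 13, more than the real one. The Y-linked gene Ddx3y ran from 0 to 62.1 CPM in TRAP cHet and from 0 to 68.09 CPM in cKO, so both groups mixed the sexes. Whether the split with 13 genes followed sex was not tested. In KO against WT neurons 1 of 35 splits, the real one, was as large (107; highest other 1), but culture numbers pair these samples, and the real split and 7 others that part every pair (highest other 0) are too few for a share under 0.05. In neurons, 2 of 35 splits were as large for added Impact against KO (1; highest other 71) and for added Impact against WT (56; 81), so chance was not excluded. In both cases the larger split set cultures 1 and 3 against 2 and 4, which points to a structure by culture number, and among the 7 other splits that part every pair the highest count was 0. In the average over regions, the split with 2516 genes set cKO 1, cKO 2, cKO 3 and cHet 1 against the rest. It kept part of the real genotype difference, so its count cannot tell of other structure among the libraries. In pituitary 3 of 10 splits gave as many (1; highest other 1), and 10 splits are too few for a share under 0.05.

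Single libraries stood apart from the rest of their group in 19 of 480 values tested (3.96%), where chance gives about 5%. In hypothalamus these were cKO 3 for Sst (101 CPM), cKO 4 for Rgs5 (21.5) and Rpl5 (26.9) and cHet 1 for Hcrt (28.0). In periaqueductal gray it was cHet 1 for Dock5 (27.3 CPM). In caudate putamen they were cKO 1 for Drd2 (137 CPM), cHet 3 for Mx1 (0.188) and cHet 2 for Serpina3n (9.01). In substantia nigra they were cKO 1 for Calcr (9.19), Scn4b (29.2) and Hmgcs1 (777), cKO 4 for Col1a1 (39.2) and cHet 4 for Th (865) and Pvalb (210). In primary neurons they were KOImpact 4 for Gja1 (72.7 CPM) and KOImpact 2 for Chac1 (13.46). In TRAP they were cKO 6 for total tags (19.1 M) and cKO 1 for Impact (14.5 CPM) and Gad2 (187 CPM).

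The effect of genotype differed between the 4 regions by the interaction test in 51 genes. The smallest adjusted p were those of Pde2a (0.000443), Dgkg (0.000897), Wfs1 (0.00135), Synpr (0.00144), Nova1 (0.00144), St8sia2 (0.00637), Htr2c (0.00637), Accn4 (0.00637), Epha10 (0.00682) and 5730419I09Rik (0.00682). In the order hypothalamus, periaqueductal gray, caudate putamen and substantia nigra, the log2 fold changes were 0.11, -0.15, 0.45 and -0.23 for Wfs1, 0.35, 0.49, -0.60 and -0.21 for St8sia2, and 0.14, 0.21, 0.24 and 0.77 for the serotonin receptor gene Htr2c. They were 0.06, 0.65, 0.05 and 0.73 for Accn4, -0.05, -0.03, 0.62 and -0.00 for Epha10, and -0.09, -0.02, -0.52 and 0.01 for 5730419I09Rik.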

How the results depend on the processing

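The runs without Rn45s and Lars2, without the interferon list and with Impact contrasts paired by culture, the block with estimated correlation, and the leave-one-out of the joint region fits were chosen after seeing the data. Over all settings tried, counts of changed genes ran from 1427 to 2094 in hypothalamus, 1441 to 2176 in periaqueductal gray, 1547 to 1928 in caudate putamen and 889 to 2168 in substantia nigra, apart from leaving out libraries. The latter gave 1060 to 2058, 764 to 1520, 826 to 1939 and 705 to 1483. Without a library the counts ran from 0 to 9 in pituitary, 4 to 5 in TRAP, 46 to 103 for KO against WT neurons and 1 to 3 for added Impact against KO. They ran from 22 to 50 for added Impact against WT, 5952 to 6265 for the average over regions and 26 to 77 for the interaction. Over the other settings, which include leaving out a region, the average ran from 4804 to 6454 genes and the interaction from 3 to 151. DESeq2 called 5 genes in pituitary, 16 in TRAP, and 322, 8 and 154 in the neuron comparisons in the same order. With no filter on low counts, pituitary had 75 and added Impact against KO 2. With a replicate block the counts were 889 in substantia nigra (865 shared with the 1457), 33 in pituitary, and 942, 27 and 503 in neurons, and a random block gave 151 interaction genes (50 shared with the 51). Same-numbered samples in hypothalamus (-0.0188 to 0.0434), periaqueductal gray (0.0237 to 0.33), caudate putamen (-0.0378 to 0.285), substantia nigra (-0.261 to 0.123) and TRAP (-0.223 to 0.179) did not all deviate together, and 0, 3, 1, 1 and 1 pairs correlated best with their own number. In periaqueductal gray the block gave Nova1 -0.32 (adjusted p = 0.0156). In neurons Nova1 with added Impact against KO was 0.53 with DESeq2 (adjusted p = 2.4e-06), with no filter (0.0171) and with the block (6.26e-05), and 0.45 to 0.58 without a library. Of 66 list calls, 0 passed with an estimated correlation and 11 with fry, and with the block and an estimated correlation together 5 of the 31 in pituitary and neurons did. The covariance for reversal by Impact was -0.000389 for genes with a mean log2 CPM of at least 3 and -0.00271 when paired by culture number, against 0.00163, while the other scaling cannot move it by its construction. For these differences the cause was not tested, apart from fewer samples in the runs that left out a library.

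For 225 gene results considered for naming in the text, 3307 of 3374 values kept their call, 28 lost and 39 gained it, and 0 changed direction past the threshold. For Nova1 and Impact 274 of 280 values kept their side and 6 gained a call. For the 66 list calls 860 of 1066 values kept the call and 206 lost it. In pituitary, which had the lowest totals and n = 3, 46.3% of simulated 2-fold changes were recovered, and depth was not varied apart from n.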

Other observations

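No test in this part was planned before the values were seen. No list of histone genes was tested, and those named here were picked for their average change over the 4 brain regions. Hist1h1e, a linker histone gene, had an average log2 fold change of -1.27 (SE 0.15, adjusted p = 1.91e-08) and fell in hypothalamus from 1.74 to 0.627 CPM (-1.48, adjusted p = 0.00481), in periaqueductal gray by 1.52 (0.00928), in caudate putamen by 0.93 (0.0458) and in substantia nigra by 1.22 (0.0188). The average was -1.54 for Hist1h2be (adjusted p = 2.88e-08), -1.63 for Hist1h3d (adjusted p = 7.21e-08) and -1.24 for Hist2h3c2 (adjusted p = 2.28e-06). These are low levels, with a mean log2 CPM of 0.75 for Hist1h1e, 0.47 for Hist1h2be, -0.55 for Hist1h3d and -0.48 for Hist2h3c2. All lie under the 1 that the rule for naming genes asked. In TRAP the values were -0.08 for Hist1h1e (adjusted p = 0.931) and -0.01 for Hist1h2be (adjusted p = 0.999), and in KO against WT neurons -0.12 for Hist1h1e (adjusted p = 0.945). Hist1h1c, another linker histone gene, fell in caudate putamen (-0.64, adjusted p = 0.0211), and did not pass in hypothalamus (-0.35, 0.192), periaqueductal gray (-0.39, 0.116) or substantia nigra (-0.22, 0.439).

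Library cKO 4 of each region held the lowest Nova1 level of its group, at 51.5 CPM in hypothalamus, 108 in periaqueductal gray, 8.70 in caudate putamen and 26.1 in substantia nigra. The same libraries held the highest Hsph1 of the cKO group (256, 205, 288 and 154 CPM) and the lowest Rbm3 and Cirbp. Within a genotype, same-numbered libraries of different regions deviated together more than others, with a mean correlation of 0.175 over 48 pairs, of which 36 exceeded 0.1, against -0.0581 over 144 pairs with different numbers. The labels do not state whether a number stands for an animal.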
